A study of Mus musculus with 2 samples.

How the data were processed

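DNase-seq libraries from frontal cortex of female F1 mice (B6 by CAST) aged 36 days were analysed from the processed files that the authors deposited. The labels put both libraries in 1 group, as biological replicates 1 and 2 with separate tissue sample records. The same donor label stands on both, so whether they came from separate animals is not given in the sources used here.

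For each library the deposited files hold 2 peak lists, a list of footprints and a genome-wide table of cleavage rates with an FDR per interval. All are on the mouse build mm10, per the labels, and were made from each library's own filtered alignments, per the text listing deposited with them. The aligner, the peak and footprint callers, their versions and thresholds are not given in the sources used here. The authors' peak signal is a read-depth normalized density per peak, and it was used to rank peaks within a list and to compare the same peak between replicates. All distinct signal values of each library were whole multiples of 1 step, within 0.02 steps or the rounding of the printed digits, whichever was larger. Library totals were not analysed here, so the tags per library follow only if the step is 1 tag after scaling to tags per M (mega). The other score columns of the peak lists are constant. The authors' p-value column of the cleavage table is an FDR that ends at 0.05, and the score column of the footprint list deposited by the authors is 0.01 in every row, which gives no rank to single footprints.

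Both peak lists are named as peaks and have a median width of 200 bp, so the rule fixed before the data were examined, to take the named list or the one with the shorter median, left a tie. The list with fewer peaks and the shorter mean width was taken as the main list after the files were seen, and the other is called the longer list. Every peak of the main list held a position with an FDR of 0.001 or less, and every peak of the longer list held one of 0.05 or less, while 55.6% and 59.1% of the longer lists held one of 0.001 or less.

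Gene positions were taken from GENCODE M21 and sequence from GRCm38, the build of the files, on 21 chromosomes; all peaks and footprints lay within them. A peak was shared when it overlapped a peak of the other replicate by at least 1 bp. Random placement moved each peak of replicate 2 to a random position on its own chromosome 100 times. Peak midpoints were assigned in the order promoter (500 bp to each side of any TSS), exon, intron and intergenic. For each of 15 gene lists (274 different genes; Pvalb and Ttr are in 2 lists each) the share with a promoter peak in both replicates, and the median number of shared peaks in the gene body and 10 kb to each side, were set against 10000 random lists of protein-coding genes in the same of 10 classes of gene span. Each random list drew every gene anew from its class, with replacement, so this is a resampling test over genes and not a test over animals. These two-sided p-values were adjusted by Benjamini-Hochberg over the lists. Footprints were placed at random within the same peaks 100 times. Motifs were matched exactly on both strands to 26 consensus sequences, and the density of matches centred in footprints was divided by that in the rest of the same peaks, with intervals from 200 bootstraps over peaks and 10 shuffled versions per consensus. Intervals cover counting error only.

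The gene lists, motifs, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule took, per gene list, the 3 members with the most shared peaks (ties by symbol) and up to 3 members with no peak in either replicate, the 10 protein-coding genes with the most shared peaks, and per replicate the 3 highest peaks overall and the 3 highest without a partner. Some genes that the rule selects are not named. Genes named for a promoter peak as examples of a count, and those said to be picked later, lie outside it. The alternatives were other overlap rules, the 50% of peaks with the highest signal, equal list lengths, the longer list, 5 rank bins, TSS windows of 250 and 1000 bp, gene windows of 0 and 50 kb to each side, peaks away from TSSs, 20 bp flanks, an FDR of 0.01 and leaving out each replicate. Protein-coding genes alone, the mean in place of the median and random lists matched on promoter CpG ratio were added after the data were seen. Comparisons of gene lists and motifs between the replicates, in the closing observations, were also chosen then. The lists were set against 10000 random lists, differences between sets of lists had intervals from 2000 bootstraps over genes, and the motif and signal ratios of sets of peaks from 200 bootstraps over peaks. The list comparisons were repeated without genes whose windows overlap that of another gene of the list.

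The overlap code was tested on 5000 simulated peaks in 2 settings and returned the simulated share in both. The gene list test was tested on the 21911 genes with 0, 4 or 8 peaks added per gene of 1 list, and the motif test on 3000 peaks with simulated ratios of 1, 3 and 10, for which it returned 1, 2.99 and 10.0. Work was done in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9; sequences of peaks were compared with BLAST+ 2.17.0. Reads of the B6 and CAST alleles cannot be told apart in these files, so allelic differences were not analysed here.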

Results

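DNase-seq was carried out on the frontal cortex of 36-day-old female F1 mice of a cross between the B6 and CAST strains. In this assay DNase I cleaves nuclear DNA where nucleosomes and other proteins leave it exposed, and regions with many cleavage events are called as peaks of accessible chromatin. The labels give 1 group with 2 biological replicates, taken from separately recorded tissue samples, and no other condition, so the comparison the design allows is between the 2 replicates. The signal of a peak, a density normalized for read depth by the authors, was a whole multiple of 0.01178 in replicate 1 and of 0.00971 in replicate 2. If this step is the value of 1 tag after scaling to tags per M (mega), the libraries held 84.9 M and 103 M tags, a 1.21-fold difference. The intervals given for shares of peaks are 95% Wilson intervals and cover counting error only.

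The first comparison asked how much of the genome was called accessible in each replicate. Replicate 1 had 29700 peaks and replicate 2 had 66512, a mean of 48106 ± 26030 (SD, n = 2), so replicate 2 had 2.24-fold more. The peaks covered 6.42 Mb in replicate 1 and 14.7 Mb in replicate 2, or 0.242% and 0.554% of the genome, with a median width of 200 bp in both. The authors' second and longer peak list held 56015 and 117579 peaks, a 2.10-fold difference. With 2 replicates this spread can only be described, and no test between groups exists.

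Peaks of the smaller list were almost all found again in the larger one. Of the replicate 1 peaks, 92.5% (95% interval 92.2 to 92.8%) overlapped a replicate 2 peak by at least 1 bp, against 1.21% on average when the replicate 2 peaks were placed at random on the same chromosomes 100 times (highest 1.38%). In the other direction 40.7% (40.3 to 41.0%) of the replicate 2 peaks overlapped a replicate 1 peak, against 0.513% at random. The base pairs of the lists had a Jaccard index of 33.2%. When the replicate 2 list was shortened to its 29700 peaks of highest signal, 75.8% of replicate 1 peaks and 74.2% of these replicate 2 peaks were shared. Of the 39458 replicate 2 peaks without a partner, 16872 (42.8%) overlapped a peak of the longer list of replicate 1.

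Sharing followed the rank of a peak within its own list. Each list was divided into 10 bins by signal. In replicate 1 the highest bin was shared in 99.7% of cases and the lowest bin in 72.3%. In replicate 2 the same bins gave 99.0% and 2.84%, a difference of 96.2 percentage points, and the share fell from each bin to the next. The median signal of replicate 2 peaks was 2.29 where they had a partner and 0.845 where they had none.

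**Figure D1:**
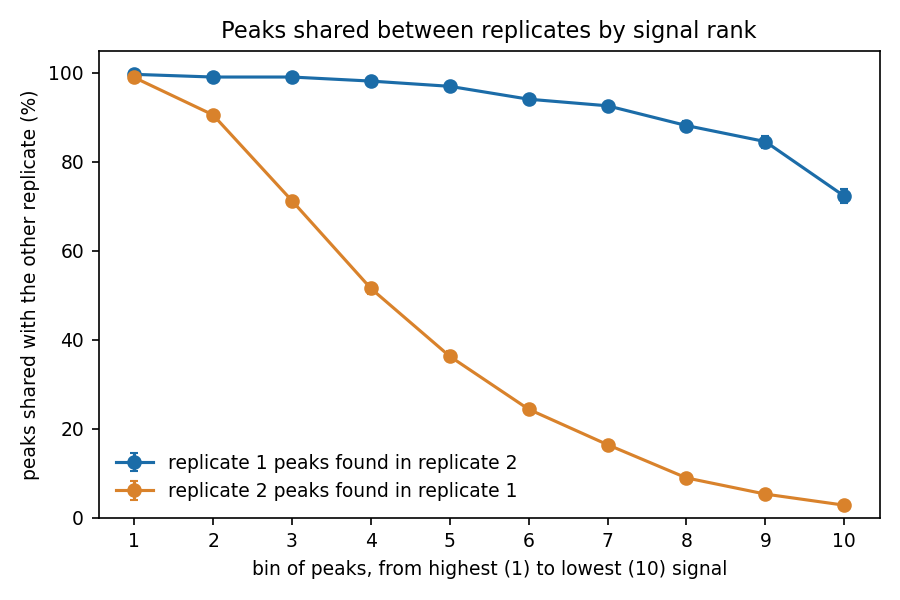
Percentage of peaks shared with the other replicate (vertical axis) in 10 bins of peaks ordered from highest to lowest signal within each replicate (horizontal axis); bars are 95% Wilson intervals. Replicate 1 falls from 99.7% to 72.3%, and replicate 2 from 99.0% to 2.84%.

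At the 27469 replicate 1 peaks with a partner, the depth-normalized signal was higher in replicate 2 in 96.4% of pairs. The median log2 ratio of replicate 2 to replicate 1 was 0.69 (quartiles 0.45 and 0.91), or 1.61-fold. It was 0.76 at the 13961 shared promoter peaks and 0.61 at the 11610 shared peaks farther than 1000 bp from any transcription start site (TSS). The log2 signals of the pairs correlated across peaks (Pearson r = 0.93), which are not independent replicates.

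Promoters held a far larger part of the peaks than of the genome. Peaks with their midpoint within 500 bp of an annotated TSS were 51.2% of the list in replicate 1 and 31.3% in replicate 2, a mean of 41.2 ± 14.1% (SD, n = 2), where such windows make up 3.26% of the genome. Introns held 21.1% and 33.2% of the peaks, intergenic sequence 23.0% and 30.02%, and exons 4.79% and 5.53%. The promoter share followed the signal, from 84.9% in the highest of the 10 bins to 30.8% in the lowest in replicate 1, and from 84.7% to 12.9% in replicate 2. Peaks of replicate 2 without a partner were in promoters in 18.1% of cases and in introns in 41.3%, against 50.5% and 21.4% for its shared peaks. Among the 29700 highest peaks of replicate 2 the promoter share was 47.5%.

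Of 21911 protein-coding genes, 11173 had a peak within 500 bp of a TSS in replicate 1, 13150 in replicate 2 and 11136 (50.8%) in both. Genes that neurons switch on with activity and genes needed by every cell had open promoters in nearly every case. Of 20 activity-regulated genes, which include the immediate early genes Fos, Junb, Egr1 and Arc, 19 had a promoter peak in both replicates, and Npas4, a neuronal transcription factor, had it in replicate 2 alone. All 20 housekeeping genes, such as Actb, Gapdh and Tbp, had a promoter peak in both. Random lists matched on gene span had a median of 40% and 45% for these lists, and both lists lay above them (adjusted p of 0.0006 each, adjusted over the 15 lists alone; both had an unadjusted p of 0.0002, the smallest that 10000 random lists can give). Of 20 genes for synapse proteins and ion channels, 18 had a promoter peak in both replicates, among them Syn1, Snap25, Dlg4, Grin1, Grin2b and Scn1a. This share of 90% was above the random median of 70%, with an adjusted p of 0.0505 that missed the threshold. Against random lists matched instead on the CpG ratio of the promoter, an alternative added after the data were seen, the list lay above them (adjusted p of 0.0035). It was not called under any of the other alternatives, with adjusted p from 0.054 with replicate 1 alone to 0.811 with the 50% of peaks of highest signal, where its share fell to 0.55 of the genes.

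Of 20 genes marking excitatory neurons, 9 had a promoter peak in both replicates, among them Tbr1, Cux1, Bcl11b, Rorb and Camk2a. A further 9 had one in replicate 2 alone, including Fezf2, Foxp2, Emx1 and Mef2c, transcription factors of cortical projection neurons. The promoters of the remaining excitatory markers, Neurod2 and Slc17a7, had no peak in either replicate. The count in both replicates was within the range of random lists, on their lower side (adjusted p of 0.348). With replicate 2 alone the share of 0.9 was on their upper side and missed the threshold (adjusted p of 0.0513). Of 20 genes marking inhibitory neurons, 3 had a promoter peak in both (Adarb2, Erbb4 and Maf), which was below random lists (adjusted p of 0.00262), and 9 more had one in replicate 2 alone, among them Dlx2, Dlx5, Sp9, Npy and Pvalb. In replicate 2 taken alone, 12 of 20 inhibitory genes had one, on the upper side of random lists and not called (adjusted p of 1). The promoters of Gad1 and Gad2, the enzymes that make GABA, of Slc32a1, which loads it into vesicles, and of Sst and Vip had no peak in either replicate.

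Of 20 oligodendrocyte lineage genes, 4 had a promoter peak in both replicates (Olig1, Pdgfra, Myrf and Fa2h), fewer than random lists (adjusted p of 0.0075), and 5 more had one in replicate 2 alone (Mbp, Cnp, Olig2, Cldn11 and Ugt8a). With replicate 2 alone the count of 9 was not below random lists (adjusted p of 0.237). Of 20 astrocyte genes, 7 had a promoter peak in both, among them Gfap, Slc1a3, Sox9 and Gja1, within the random range (adjusted p of 0.209). With the 50% of peaks of highest signal in each list, the astrocyte list fell below random lists (adjusted p of 0.0182). Microglia had 2 of 20 (adjusted p of 0.000857) and vascular cells 0 of 20 (adjusted p of 0.0006), both below random lists. The microglia call was lost against lists matched on promoter CpG ratio (adjusted p of 0.139), and the vascular call was not (adjusted p of 0.001).

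Lists for other brain regions and organs served as a comparison. Of 12 striatal genes, 5 had a promoter peak in both replicates (among them Drd1, Foxp1, Pde10a and Rgs9), within the random range (adjusted p of 0.645), and 5 more, including Drd2 and Adora2a, had one in replicate 2 alone. The choroid plexus list had 1 of 10 (Prlr; adjusted p of 0.0153) and the list of hindbrain and posterior patterning genes, mostly Hox genes, 0 of 14 (adjusted p of 0.00267). Liver genes had 0 of 20 (adjusted p of 0.0006), skeletal muscle genes 1 of 20 (Mylpf; adjusted p of 0.0006) and lymphoid and erythroid genes 1 of 20 (Tal1; adjusted p of 0.000857), all below random lists. The calls for choroid plexus and liver were lost with the CpG-matched lists (adjusted p of 0.105 for each), and those for the other lists in this paragraph that lay below random lists remained.

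**Figure D2:**
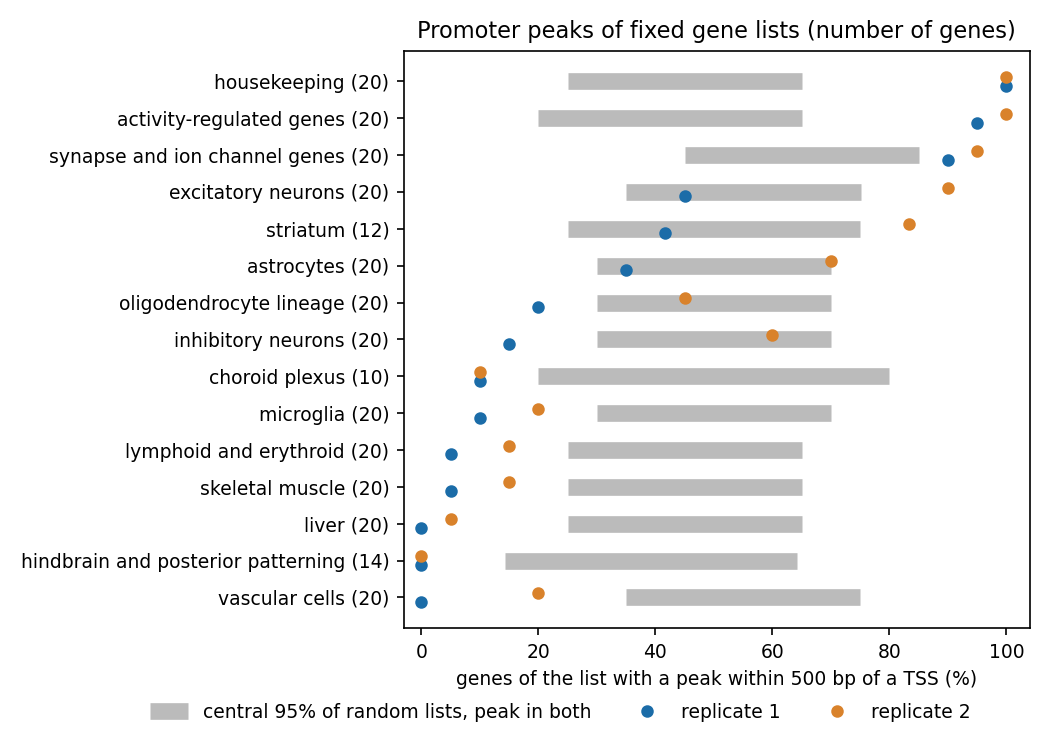
Percentage of the genes of each fixed list with a peak within 500 bp of a TSS (horizontal axis) in replicate 1 and replicate 2; grey bands hold the central 95% of 10000 span-matched random lists, for a peak in both replicates. No list member had a promoter peak in replicate 1 alone, so the replicate 1 points equal the counts for both, from 0 of 20 vascular genes to 20 of 20 housekeeping genes.

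Counts of peaks over whole gene neighbourhoods, the gene body and 10 kb to each side, gave fewer calls by the median. The inhibitory, choroid plexus, posterior patterning, liver and muscle lists had a median of 0, the lowest possible. Span-matched random lists reached 0 too often in this window for any call below them. For these lists the median could therefore not test for fewer peaks. Housekeeping genes had a median of 3 shared peaks (random median 1, adjusted p of 0.009), the highest of the 15 lists and the only median past the threshold. That call was lost with the gene body alone (adjusted p of 0.322), with 50 kb to each side (0.107), with replicate 2 alone (0.059), without peaks near a TSS (1, on the lower side of random lists) and with CpG-matched lists (0.09). Activity-regulated genes had a median of 2 (adjusted p of 0.211). Their call passed the threshold with replicate 2 alone (adjusted p of 0.003), with the 50% of peaks of highest signal (0.036) and without peaks near a TSS (0.042). Excitatory neurons, on the lower side of random lists by their shared peaks, passed it above them with replicate 2 alone (0.009). Inhibitory neurons passed it below random lists with 50 kb to each side (0.033) and with CpG-matched lists (0.0045), as did posterior patterning genes with the latter (0.003). With the mean in place of the median, a choice made after the data were seen, activity-regulated genes (2.75 shared peaks) and housekeeping genes (2.6) lay above random lists (adjusted p of 0.003 each). Inhibitory neurons (0.6; adjusted p of 0.015), vascular cells (0.75; adjusted p of 0.0264), choroid plexus, hindbrain and liver lay below. On simulated data the median recovered a list with 8 added peaks per gene and missed a list with 4 added. The simulated genes had more peaks than the real ones, whose median was 1 shared peak. The simulation therefore does not give the size of difference that could be found in the real counts.

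Among the markers, the genes below were among those with the most shared peaks in their lists. Ties were taken in alphabetical order, so further genes had the same counts, such as Sox9 in the astrocyte list with 3 and Ckm and Tnnc2 in the muscle list with 2. Tbr1, a transcription factor of deep-layer cortical neurons on chromosome 2 from 61802930 to 61814114, had 9 shared peaks, Cux1 had 8 and Cux2 had 4. The 10 Tbr1 peaks of replicate 1 had signals from 0.695 to 1.06, below the median of 1.34 of that list. In the inhibitory list Maf had 4, and Erbb4, a neuregulin receptor, and Nxph1 had 2 each, while Dlx1, Gad2 and Lhx6 had no peak in either replicate. Aldh1l1 (5), Clu (3) and the glutamate transporter gene Slc1a3 (3) were among the first in the astrocyte list. In the oligodendrocyte list Fa2h, Mbp and Myrf had 2 each, and Aspa, Mag and Nkx6-2 had no peak. Cx3cr1, the fractalkine receptor gene of microglia, had 8 and Spi1 had 2, whereas Gpr34, Itgam and Siglech had none in either replicate. Of the vascular genes, Flt1 and Vtn had 3 and Cdh5 had 2, and Anpep, Cldn5 and Ly6c1 had none. Such windows can hold promoters of neighbouring genes. Aldh1l1, Cx3cr1 (annotated over 168 kb), Spi1, Flt1, Vtn and Cdh5 had shared peaks in their windows but no promoter peak in either replicate.

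In the activity-regulated list Egr2 had 7 shared peaks and Fos and Junb had 6 each. The calcium channel gene Cacna1c had 9 and the NMDA receptor gene Grin2a had 4. In the housekeeping list Eif4a2 had 4. In the striatal list Pde10a had 6 and Foxp1 had 3, and Isl1 had no peak. In the comparison lists Kcne2 (2), Prlr (1) and Slc4a5 (1) were among the first for choroid plexus, Hoxd4 (2), Hoxa9 (1) and Hoxb9 (1) for posterior patterning, and Apoa2 and Hnf4a (2 each) for liver. Mylpf (3), Acta1 (2) and Actn3 (2) were among the first for muscle, and Klf1 (3), Pax5 (3) and Cd4 (2) for blood. No peak in either replicate lay near Folr1, Otx2, Ttr, En1, Hoxa2, Hoxa5, Ahsg, Cyp2e1, Cyp3a11, Myh4, Myod1, Myog, Alas2, Cd3d or Gata1.

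**Figure D3:**
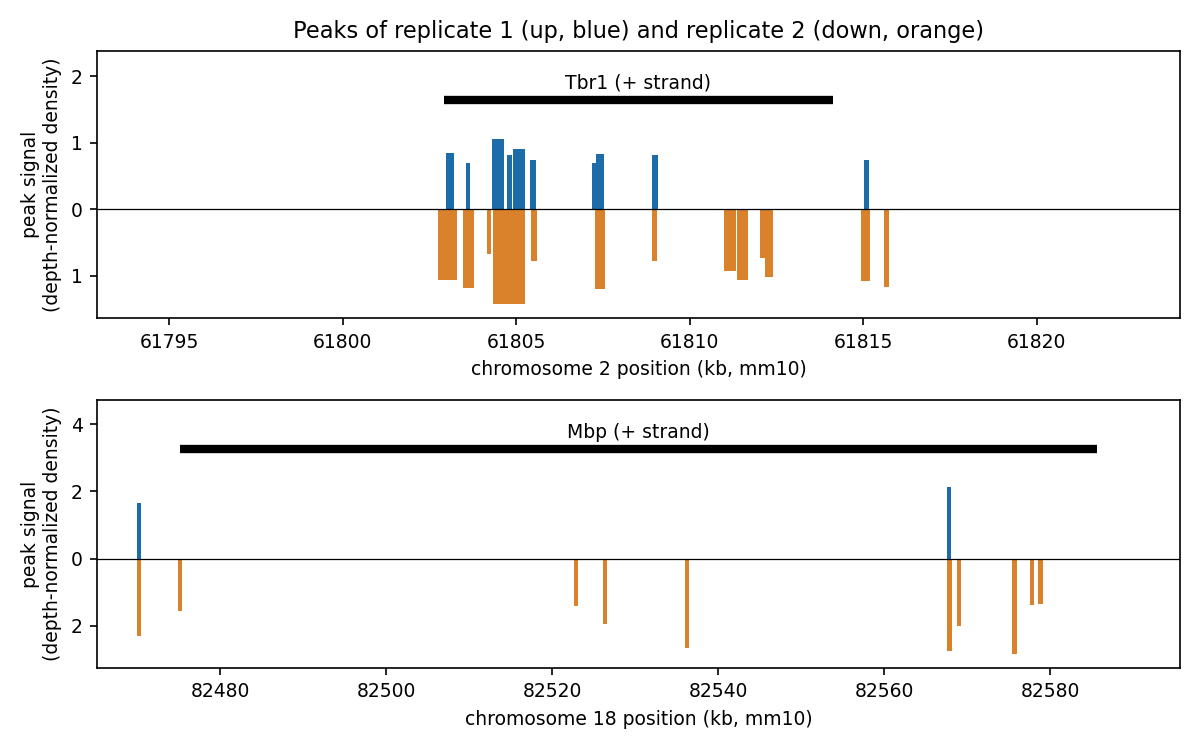
Peaks over the neuronal gene Tbr1 and the myelin gene Mbp with 10 kb to each side, by position (horizontal axis, kb) and depth-normalized signal (vertical axis), with replicate 1 upward and replicate 2 downward; black bars are the annotated genes. Tbr1 had 10 peaks in replicate 1 and 15 in replicate 2, some of which overlap each other and were counted separately, and Mbp had 2 and 10.

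Peaks around genes were more numerous in replicate 2. The median per gene was 1 in replicate 1 and 7 in replicate 2 for excitatory neurons, 0 and 2 for inhibitory neurons, 2 and 6 for synapse genes and 2 and 7 for activity-regulated genes. It was 1 and 3 for the oligodendrocyte lineage, 1 and 2 for microglia, 0 and 1.5 for vascular cells and 3 and 3.5 for housekeeping genes. Random lists of the same spans also gained peaks. Gains were tested by the log2 ratio of the summed peak counts of each list, not by these medians. The gains of excitatory (adjusted p of 0.151), synapse (0.234) and activity-regulated genes (0.187) did not pass the threshold against random lists. Those of inhibitory neurons (0.003) and the oligodendrocyte lineage (0.018) did. Without genes with overlapping windows the inhibitory gain no longer passed it (adjusted p of 0.0765). Genes with 0 peaks in replicate 1, picked after their values were seen, included Fezf2 (11 peaks in replicate 2) and Dlx5 (14).

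Over all protein-coding genes, long genes had the most shared peaks in their windows, counts that were not corrected for gene span. Gm20388, a gene model of 4435 kb on chromosome 8, had 117, and Fgfr2, a fibroblast growth factor receptor gene annotated over 2961 kb, had 55. Camta1 had 27, Auts2 and Pde4d had 20 each, Maml3 had 16, B4galt5 and Gm37240 had 15, and the ion channel gene Asic2 and the protocadherin gene Pcdh17 had 13. B4galt5 and Pcdh17 were the shortest of these, at 50.7 and 95.4 kb. A window over a long annotation also counts peaks of other genes inside it, such as Irf8 and Acta1 within Gm20388. The median over all 21911 genes was 1 shared peak, and 4785 genes had no peak in either replicate.

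The same 3 places held the peaks of highest signal in both replicates. The first lay on chromosome 17 from 39846781 to 39846920, in an exon of CT010467.1, with a signal of 76.9 in replicate 1 and 91.1 in replicate 2. The second lay in an exon of Lars2, the gene of the mitochondrial leucyl-tRNA synthetase, on chromosome 9 near 123461881 (48.2 and 45.8). The third was intergenic on chromosome 3 from 5860361 to 5860530 (41.9 and 44.1). None of the 20 highest peaks of either replicate aligned to the mitochondrial genome. Copies of them elsewhere in the nuclear genome were not looked for, so whether these signals reflect accessibility or repeated sequence was not tested. At Lars2 the signal was lower in replicate 2, unlike at the 96.4% of shared pairs that were higher there. The highest peaks without a partner were lower. In replicate 1 they lay within 500 bp of a TSS of Ppp1r10 (3.79), Fars2 (3.48) and Brat1 (3.46), and in replicate 2 of Tpr (9.30), Tle1 (8.20) and Cry1 (6.56), a gene of the circadian clock. All 6 were also missing from the longer list of the other replicate.

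The X chromosome had fewer peaks per Mb than the autosomes. Autosomes had 12.1 peaks per Mb in replicate 1 and 27.1 in replicate 2, and X had 4.42 and 9.68, so the ratio of X to autosomes was 0.366 and 0.357 (mean 0.362 ± 0.00592 SD, n = 2). For the 50% of peaks with the highest signal the mean ratio was 0.227. The Y chromosome had 8 peaks in replicate 1 and 17 in replicate 2, or 0.0908 and 0.193 per Mb, in libraries labelled female. The Y genes Ddx3y, Kdm5d, Uty and Eif2s3y had no promoter peak in the longer list of either replicate, while the X copies Ddx3x, Kdm5c, Kdm6a and Eif2s3x had one in the longer list of both.

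Footprints are short stretches inside accessible DNA that are shielded from cleavage, as by a bound protein. The authors called 112826 of them in replicate 1 and 250543 in replicate 2 (2.22-fold; mean 181684 ± 97381 SD, n = 2), with a median width of 9 bp in both. Peaks of the main list contained 64.5% and 66.4% of them, and peaks of the longer list 87.6% and 86.9%. Per length of peak the replicates did not differ, with 11.3 footprints per kb in each, and 82.5% and 82.4% of merged peaks held at least 1. Of the 71670 replicate 1 footprints in shared peaks, 60.2% overlapped a replicate 2 footprint, against 33.3% on average (highest 33.7%) in 100 random placements within the same peaks. With 50% reciprocal overlap the share was 37.9%, against 11.8% at random.

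Footprints held the binding motifs of several factors at densities far above the rest of the same peaks. The motif of NRF1, a regulator of mitochondrial and growth genes, was 41.3 times as dense inside footprints in replicate 1 (95% bootstrap interval 31.9 to 59.8) and 102 times in replicate 2 (71.5 to 176). The motif of CTCF, which sets boundaries of chromatin domains, was 37.6 times (33.3 to 41.8) and 57.6 times (52.3 to 64.9) as dense. CREB/ATF, bound by activity-responsive factors, had ratios of 9.97 (8.59 to 11.6) and 16.6 (14.2 to 19.7), and RFX had 9.71 (5.32 to 16.4) and 9.74 (7.11 to 13.4). The neurogenic bHLH motif, bound by factors such as Neurod2 and Neurod6, had 2.78 (2.50 to 3.08) and 3.36 (3.14 to 3.58). Of 26 motifs, 11 were above 1 in both replicates by their intervals, the others of these being NFI, EGR, SP/KLF, YY1, ETS and NFY. For SP/KLF the base-shuffled consensus gave 4.04 and 4.98 beside 4.36 and 6.39 for the motif, and the intervals overlapped in at least 1 replicate, so 10 of the 11 also exceeded their shuffled versions. RFX, 1 of these 10, could not fail this comparison, since its shuffled versions had no match in footprints (ratios of 0 in both replicates). NFI rested on 9 and 19 matches inside footprints, and ETS and NFY were no longer above 1 by their intervals in peaks farther than 1000 bp from a TSS (mean ratios 1.90 and 0.951) or against 20 bp flanks (1.76 and 0.942). In peaks away from a TSS the mean ratio fell from 71.6 to 32.5 for NRF1, from 13.3 to 5.66 for CREB/ATF and from 5.37 to 3.34 for SP/KLF. Against flanks it fell from 47.6 to 30.5 for CTCF.

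Some other motifs were rarer inside footprints than outside. FOX (0.228 and 0.315), POU (0.182 and 0.509), LHX/DLX homeodomain (0.283 and 0.417), GATA (0.419 and 0.450), TEAD (0.582 and 0.672) and IRF (0.729 and 0.570) were below 1 in both replicates. Against 20 bp flanks the mean ratio of IRF was 0.679, beside 0.650 in the main comparison, and its interval reached 1 in at least 1 replicate. Shuffled versions of the AT-rich motifs were also below 1, for example 0.373 and 0.434 for FOX and 0.535 and 0.568 for POU. Those of IRF were lower than IRF itself (0.290 and 0.390), by the intervals in both replicates. AP-1, the motif of Fos and Jun proteins, was below 1 in replicate 1 (0.619, interval 0.510 to 0.726) and above 1 in replicate 2 (1.12, interval 1.05 to 1.20). MEF2, a motif of neuronal activity-dependent factors, had 0.256 (0 to 0.587) and 1.06 (0.777 to 1.38). REST, a repressor of neuronal genes, had 3 and 13 matches in footprints, with ratios of 0.930 (0 to 2.49) and 3.36 (1.49 to 6.46). Its shuffled versions had ratios of 1.77 and 4.33. PU.1, of blood and microglia, had 0 and 1 match inside footprints.

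**Figure D4:**
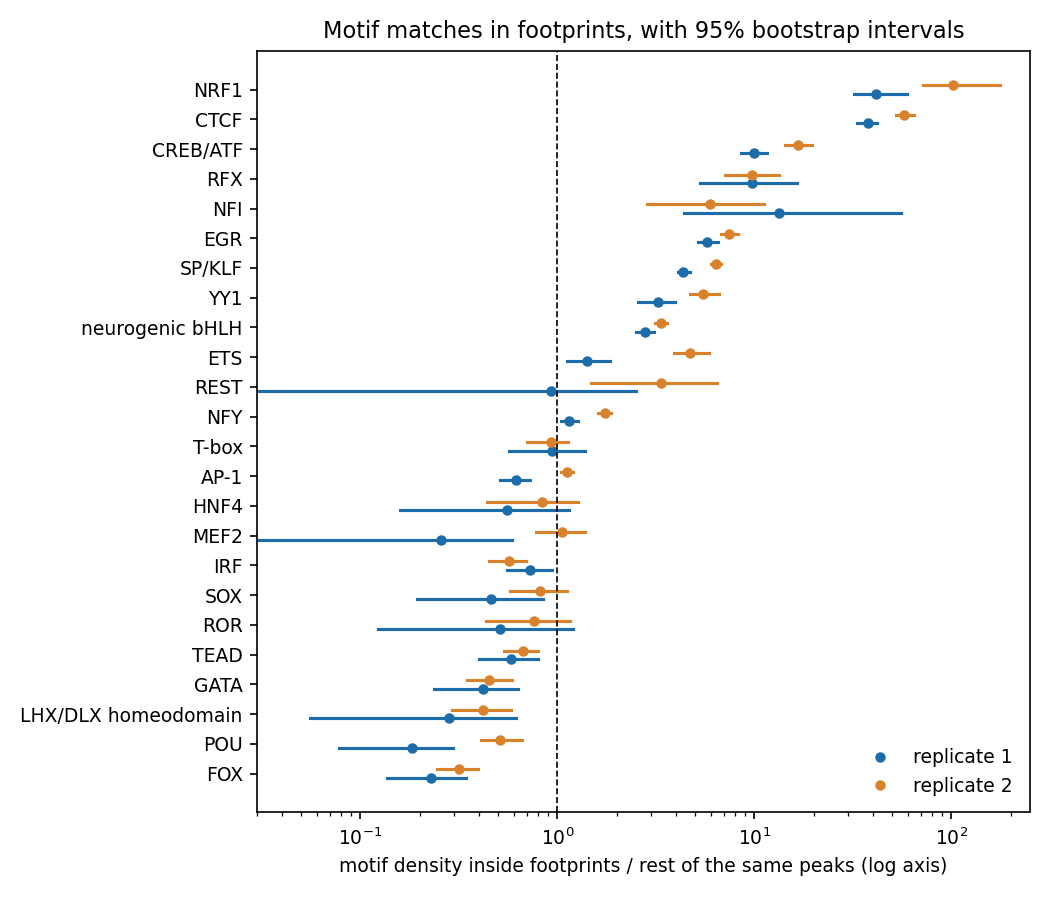
Density of each motif inside footprints divided by that in the rest of the same peaks (horizontal axis, logarithmic) in replicate 1 and replicate 2, with 95% bootstrap intervals as lines, drawn to the left edge where they reach 0; the dashed line marks a ratio of 1. NRF1 (41.3 and 102) and CTCF (37.6 and 57.6) stand farthest to the right, and FOX (0.228 and 0.315) is at the bottom; motifs with at most 1 match inside footprints in each replicate are left out.

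The genome-wide tables of cleavage rates gave the same order of the replicates. Positions at a false discovery rate (FDR) of 0.05 or less covered 18.2 Mb in replicate 1 and 41.2 Mb in replicate 2 (2.26-fold; mean 29.7 ± 16.2 Mb SD, n = 2), and at 0.001 or less they covered 9.40 and 22.6 Mb. Of the base pairs at FDR 0.05 in replicate 1, 95.9% were also called in replicate 2, and 42.5% the other way round.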

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

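The mean in place of the median and the CpG-matched random lists were tests chosen after the results were seen. With 2 replicates the spread of each value is set by 2 numbers, so the limits below are descriptive. Left as single replicates, the peak count ran from 29700 to 66512 and the footprint count from 112826 to 250543. The mean peak count was 24053 for the 50% of peaks with the highest signal and 86797 in the longer list. The share of replicate 1 peaks found in replicate 2 was 88.0% for overlap of 50% of the peak's length, 68.0% for 50% reciprocal overlap, 98.4% for the 50% of peaks with the highest signal, 75.8% at equal list lengths and 89.1% in the longer list. The difference between the highest and lowest rank bins of replicate 2 was 93.6 points for overlap of 50% of the peak's length and 90.7 points with 5 bins. The ratio of X to autosomes was 0.227 for the 50% of peaks with the highest signal and 0.369 in the longer list. The overlap of footprints was 37.9% with 50% reciprocal overlap.

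The number of gene lists past the threshold for peaks around genes, 1 as reported, was 0 with the gene body alone, 2 with the 50% of peaks of highest signal, 1 or 2 with single replicates, 2 with CpG-matched random lists and 7 with the mean. With replicate 2 alone the 2 lists were excitatory neurons and activity-regulated genes, and housekeeping genes were no longer among them. For shuffled consensus sequences 3 motifs were above 1 in both replicates, against 11. The causes of these changes were not tested, except that shorter or longer lists change a count by construction. For single lists and motifs, 243 of 274 values under alternatives stayed on their side of the threshold, 11 lost and 15 gained a call in the same direction, and 5 changed direction. NFY fell to 0.942 against flanks and 0.951 away from TSSs, the share of inhibitory promoters was 0.15 with replicate 1 alone and 0.6 with replicate 2 alone, the median of excitatory neurons 1 and 7, and housekeeping genes fell to a median of 0 without peaks near a TSS. Values not called under either setting also crossed their middle, such as T-box from 0.935 to 1.09 away from TSSs. The count of lists called for promoter peaks was 9 to 12 under its 7 alternatives, against 11, the promoter share ran from 31.3 to 55.3%, and the cleavage table from 18.2 to 41.2 Mb. Leaving out either of 2 replicates cannot move a mean by 1 SD, so it does not test these values. Replicate 1 alone hardly tests the lists called for promoter peaks either, since no list member had a promoter peak in replicate 1 alone. Its values for the 15 lists are counted among the 274. The ranking of footprints by score was not run, since the score is constant. No paired analysis was possible because the design has 1 group.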

Other observations

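The comparisons of gene lists and motifs between the replicates in this part, and the tests of depth, of promoter signal and of Y sequences, were chosen after the results they bear on had been seen, as were the genes and regions named here. Genes of the oligodendrocyte lineage gained more peaks in replicate 2 than random lists of the same gene spans. The oligodendrocyte list had 17 peaks in replicate 1 and 61 in replicate 2 (log2 ratio 1.81, random lists 0.36 to 1.40, adjusted p of 0.018 over 15 lists), with 2 and 10 at Mbp and 0 and 6 at Cnp, both genes of myelin. The inhibitory list had 12 and 70 (log2 ratio 2.50, random lists 0.47 to 1.51, adjusted p of 0.003), but its counts include neighbouring homeobox genes of forebrain interneurons whose windows overlap, Dlx1 with Dlx2 and Dlx5 (0 and 14) with Dlx6 (0 and 6). Counted once, its peaks were 12 and 64. Without these 4 genes they were 12 and 43, and the list no longer passed the threshold (log2 ratio 1.80, random lists 0.46 to 1.57, adjusted p of 0.0765). No windows overlapped within the oligodendrocyte list, which had an adjusted p of 0.021 in that comparison. With all genes the other 13 lists missed the adjusted threshold. Of these, skeletal muscle (1.65, random lists 0.33 to 1.42, adjusted p of 0.054), striatum (1.80, 0.40 to 1.73, 0.127) and lymphoid and erythroid genes (1.48, 0.37 to 1.46, 0.141) lay above the central 95% of random lists, muscle and lymphoid genes no longer so without genes with overlapping windows, and excitatory neurons (1.64, adjusted p of 0.151) and microglia (0.77, 0.889) lay inside it. With the replicate 2 list shortened to 29700 peaks, the oligodendrocyte list still gained, with 17 and 33 peaks (log2 ratio 0.94, adjusted p of 0.027), and the inhibitory list had 12 and 13 (0.11, adjusted p of 0.997).

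The AP-1 motif was denser in distal peaks that replicate 2 alone had. Among the 29700 highest peaks of replicate 2, 2488 were missing from the longer list of replicate 1, and the 1604 of them farther than 1000 bp from a TSS held 0.659 AP-1 matches per kb. The 8731 distal peaks shared at this list length held 0.349 per kb, a ratio of 1.89 (95% bootstrap interval 1.56 to 2.21), at nearly equal GC content (54.2% and 54.3%). In the 3598 distal replicate 1 peaks without a partner among the 29700 highest peaks of replicate 2, the ratio was 1.10 (0.933 to 1.26). Only 2231 replicate 1 peaks had no partner in the whole main list of replicate 2, so many of these 3598 overlapped a replicate 2 peak of lower signal. TEAD was also denser in the replicate 2 set, with a ratio of 1.51 (1.05 to 2.16), and NFY was rarer (0.673, 0.457 to 0.938). CTCF was rarer in both sets, with ratios of 0.344 (0.288 to 0.419) and 0.561 (0.493 to 0.618). The replicate 1 set had a lower GC content (52.6%), and in it GATA (1.52, interval 1.06 to 2.06) and the LHX/DLX homeodomain motif (2.03, 1.19 to 3.72) were denser, while CREB/ATF (0.536), EGR (0.532), SP/KLF (0.630), NRF1 (0.288, on 3 matches), ETS (0.192, on 1 match) and YY1 (0.192, on 1 match) were rarer by their intervals. The 26 motifs were compared without adjustment, and the sets were defined by different lists of the other replicate. Nor were the sets matched on signal. The 2488 peaks of replicate 2 alone had a median signal of 1.54, against 2.25 for its 29700 highest peaks. Motif differences that go with signal can therefore not be told apart from differences between the replicates.

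Some genes had many peaks of 1 replicate alone. In replicate 2, Gse1, Myo1d and Zmynd8 had 11, 11 and 10 peaks found there alone, and Dmtn and Rara, the retinoic acid receptor alpha gene, had 8 each and no peak in the main list of replicate 1. In replicate 1, 17 peaks found there alone lay within 45.5 kb on chromosome 7 from Ttyh1 to Cdc42ep5, where replicate 1 had 23 peaks and replicate 2 had 7. Their median signal was 0.424, below the 10th percentile of 0.707 of the replicate 1 list. Another 12 lay between Thra and Nr1d1, the genes of a thyroid hormone receptor and of a clock repressor, where replicate 1 had 20 and replicate 2 had 14. Their median signal was 0.801, against 1.34 for all replicate 1 peaks. The 1810 replicate 1 peaks missing from the longer list of replicate 2 had a median width of 101 bp, and 46.7% overlapped an exon, against 47.4% of all its peaks. The 2488 of replicate 2 had a median width of 200 bp, and 27.3% overlapped an exon, against 47.2% of its 29700 highest peaks. These shares count any overlap with an exon, also at promoters, unlike the exon shares by peak midpoint given earlier. Whether they differ apart from promoter peaks was not tested.

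Replicate 2 had 2.24-fold more peaks at a 1.21-fold larger number of tags, if the signal step is 1 tag per M (mega) tags. Sequencing depth alone would leave the depth-normalized signal of shared peaks equal, and its median log2 ratio was 0.69 (interval 0.68 to 0.69), which argues against it. A lower signal over background in replicate 1 is a candidate explanation, since shared promoter peaks, which most cell types have in common, were also higher in replicate 2 (median log2 ratio 0.76, interval 0.75 to 0.76). As 96.4% of all shared peaks were higher in replicate 2, this test had little room for another outcome. No biological explanation was tested for this pattern.

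Neuronal lists (excitatory, inhibitory and synapse genes) had 114 peaks in replicate 1 and 375 in replicate 2, and microglial and vascular lists 43 and 88, a difference in log2 ratio of 0.69 (interval 0.22 to 1.14) that is not corrected for gene span, for which random lists had medians of 1.17, 0.95 and 1.21 against 0.80 and 0.97. With equal list lengths, which takes away weak peaks that may cross a calling threshold, the difference was 0.48 (interval 0.00 to 0.98, its lower end just below 0), and without genes with overlapping windows, a test added later, 0.52 (interval 0.03 to 1.04). At shared distal peaks, with the log2 signal ratio corrected for mean signal, the lists differed by 0.10 (interval -0.03 to 0.28, with 39 and 27 peaks). In the longer lists they differed by 0.09 (interval -0.04 to 0.23, with 118 and 51 peaks). The single lists behind the 0.10 went different ways. Synapse genes had 0.15 (0.04 to 0.33), excitatory neurons 0.004 (-0.11 to 0.22) and inhibitory neurons -0.14 (-0.54 to 0.25). Microglia had -0.07 (-0.10 to -0.01) and vascular cells 0.01 (-0.30 to 0.16). What each planned test would show was written before its value was seen, but the pattern was noticed from the counts, and the reading of the first and second explanation below was made stricter after the values were seen, since as first written an interval holding 0 was enough to count for them. As the planned intervals hold both 0 and the sizes set in advance, and the later test passes them only narrowly, weak peaks at the threshold, a uniform difference in signal over background and a different mixture of cells in the tissue pieces cannot be told apart.

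Both libraries are labelled female, and together they had 25 peaks on Y, at 17 places, since the 8 peaks of replicate 1 overlap peaks of replicate 2. Male tissue in an amount that gives peaks would open the promoters of Ddx3y, Kdm5d, Uty and Eif2s3y, and 0 of the 4 had a peak, which argues against reads from male tissue. Sequence shared with other chromosomes is a candidate explanation: 17 of the 25 peaks (68%) matched another chromosome at 95% identity or more over 80% of their length, against 42 of 200 random Y intervals (21%), a comparison added after the 68% was seen. Counted by place, 11 of 17 (64.7%) had such a copy, and the 6 without one all lay beyond 90 Mb, near the end of Y, and stay open.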
